A study of Mus musculus with 2 samples.

How the data were processed

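The series holds polyA-selected RNA-seq of regulatory T cells (Treg cells, the CD4 T cell type that restrains immune responses) from a male mouse at 9 weeks of age. There are 2 libraries, given in the labels as technical replicates 1 and 2 of biological replicate 1. The RNA was fragmented by shearing, and the size range is given as 100 to 300 with no unit. Sorting markers, mouse strain, read length, strandedness and cell number are not given in the sources used here.

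For each library the authors deposited 3 tables made on the mm10 assembly. The gene and transcript tables rest on GENCODE M21 and come from transcriptome alignments, per the file lists deposited with the libraries. Per the file headers, these tables hold estimated counts, in which reads shared between features are divided by a model. Per the file headers they also hold TPM, which scales length-corrected abundance to a fixed total over all rows, and FPKM, which scales fragments by gene length and library size. Posterior mean TPM and posterior standard deviations are given in the same tables. The third deposited table holds whole-number read counts per gene on GENCODE M4, made from genome alignments. The aligner, quantifier and counter, with their versions, are not given in the sources used here. In both libraries the effective length equalled the annotated length less 49 bases, down to 0, in 100.0% of transcripts, so no fragment length distribution entered the TPM.

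Each M21 gene table has 81881 rows. Of these 55536 are annotated genes, 26248 are tRNA rows and 97 are spike-in rows. The rows that name no gene took 0.197% of the estimated counts in library 1 and 0.212% in library 2, and they were left out of totals and tests. The remaining total was 34697128 estimated counts in library 1 and 32049199 in library 2. The M4 tables total 9576557 and 8937887 counts over 22457 genes, of which 22195 matched an M21 gene by identifier without its version. Gene names, biotypes and coordinates came from GENCODE M21 on GRCm38, the release of the M21 tables. Coordinates are 1-based.

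With 1 biosample there was 1 group and no comparison between conditions. A gene counted as detected at 1 TPM or more in both libraries. Values are means ± SD of the libraries (n = 2), a spread that is technical and says nothing of other mice. Levels of 34 gene lists, 23 for cell programs and 11 for cell types, were described by the number of detected members and the median of log2(TPM + 1). That median was ranked as a percentile among 10000 random lists of the same size, drawn from protein-coding genes detected in both libraries. Genes are not replicates, so list levels, list medians of log2 ratios and correlations across genes were given no p-value. Only for the further macrophage and neutrophil lists were reads summed over genes and put to an exact binomial test. Of the listed symbols 9 had no match.

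Estimated counts were rounded to whole numbers before tests. Library sizes were scaled by edgeR's TMM factors over genes with a summed count of at least 10. The common dispersion was estimated by edgeR with both libraries as 1 group. Each gene's pair of counts was compared by an exact two-sided binomial test with Benjamini-Hochberg adjustment at 0.05, which compares these libraries and covers counting error only. PCR copies are not independent molecules, so its p-values are too small as a measure of technical noise. edgeR's quasi-likelihood test has no residual degrees of freedom with 1 library per side, so edgeR's exact test with the common dispersion was run as an alternative. Log2 ratios are library 2 over library 1 with a prior count of 0.5. List medians of these ratios were ranked among 10000 random lists whose members came from the 100 genes on either side in summed count. A count of 0 was read as allowing up to 3 reads.

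Both tests were tested on simulated data. For the binomial test, counts of 18746 genes in library 2 against library 1 were drawn from a Poisson model, which holds counting error only. The test called 33 of 50 genes changed 1.25-fold and 44 of 50 changed 1.5-fold. At 2-fold it called 46 of 50, at 4-fold 50 of 50, and it called 6 unchanged genes. Those 6 calls do not give the rate of false calls between the real libraries, which differ by more than counting error. The exact test with dispersion, run on 18746 simulated genes, called 16 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, and 0 unchanged genes. Its counts were drawn with a dispersion of 0.0227, and the test used the 0.0312 recovered from them.

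The rule for named genes was fixed before the data were examined. It takes all list members, the 15 genes with the highest mean TPM, and the 5 largest log2 ratios each way among genes past the threshold with a summed count of at least 100. Some genes under this rule are not reported here. Alternatives covered the detection minimum, pseudocount, unit, estimator, normalization by library totals or DESeq2 size factors, count filter, rounding, error model, threshold, prior count and each library alone. Chosen after seeing the data were the M4 counts in the tests, centring of log2 ratios within 50 bins of gene length, and thinning library 1 to the total of library 2. The work used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.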

Results

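The data describe the polyA-selected transcriptome of mouse Treg cells, measured in 2 technical libraries of 1 biosample. The libraries held 34697128 and 32049199 estimated counts over annotated genes. At 1 TPM or more in both libraries, 13275 genes were detected, of which 10583 are protein-coding, and their median was 22.8 TPM. Library 1 alone had 14055 such genes and library 2 had 14222. The highest level was that of Tmsb4x, which encodes the actin-binding thymosin beta 4, at 15440 ± 55.5 TPM (SD, n = 2 technical libraries, as for all values below). Other protein-coding genes with high levels were the class I major histocompatibility gene H2-K1 at 9808 ± 298 TPM, B2m at 6269 ± 275 TPM and mt-Co3 at 5677 ± 393 TPM. Tmsb10, H2-D1, Pfn1, mt-Atp6, Rps19 and Eef1a1 were also among the 15 highest. So were the noncoding genes CT010467.1 (a ribosomal RNA), Malat1, mt-Ts1 and Gm37376. The mitochondrial gene mt-Ts1 is very short, from 6870 to 6938, and its 4257 TPM rested on 1643 and 1899 estimated counts in libraries 1 and 2. Eef1a1, at a lower 3818 TPM, had 125575 and 138302. The rank of mt-Ts1 therefore rests on the length correction in TPM, not on many reads. Gm37376 lies on chromosome 19 from 5801941 to 5802393, opposite in strand to Malat1 and inside it, so its 5466 TPM and the 4563 TPM of Malat1 cannot be assigned to strands with certainty. Reads of H2-K1 and H2-D1 can likewise be divided with related class I genes.

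The Treg core list asks whether genes that characterise this cell type were expressed. All 24 members were detected, from 10.8 TPM for Itgb8 to 795 TPM for Il2rb. Foxp3, which encodes the lineage-defining transcription factor, stood at 109 ± 1.68 TPM. Its locus is on chromosome X from 7573644 to 7595245 (GRCm38) and overlaps other annotated genes. The high-affinity interleukin 2 receptor chain Il2ra (chromosome 2, 11642807 to 11693193) stood at 368 ± 4.98 TPM, and the inhibitory receptor Ctla4 (chromosome 1, 60887000 to 60915832) at 223 ± 2.65 TPM. Ikzf2, encoding Helios, was at 317 ± 11.9 TPM, and the tumour necrosis factor receptors Tnfrsf4 and Tnfrsf18 were at 670 ± 1.92 and 620 ± 19.5 TPM. The folate receptor family gene Izumo1r reached 738 ± 9.55 TPM and Lrrc32, encoding GARP, 238 ± 18.9 TPM. The list's median lay above all 10000 random lists, at percentile 100.

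**Figure D1:**
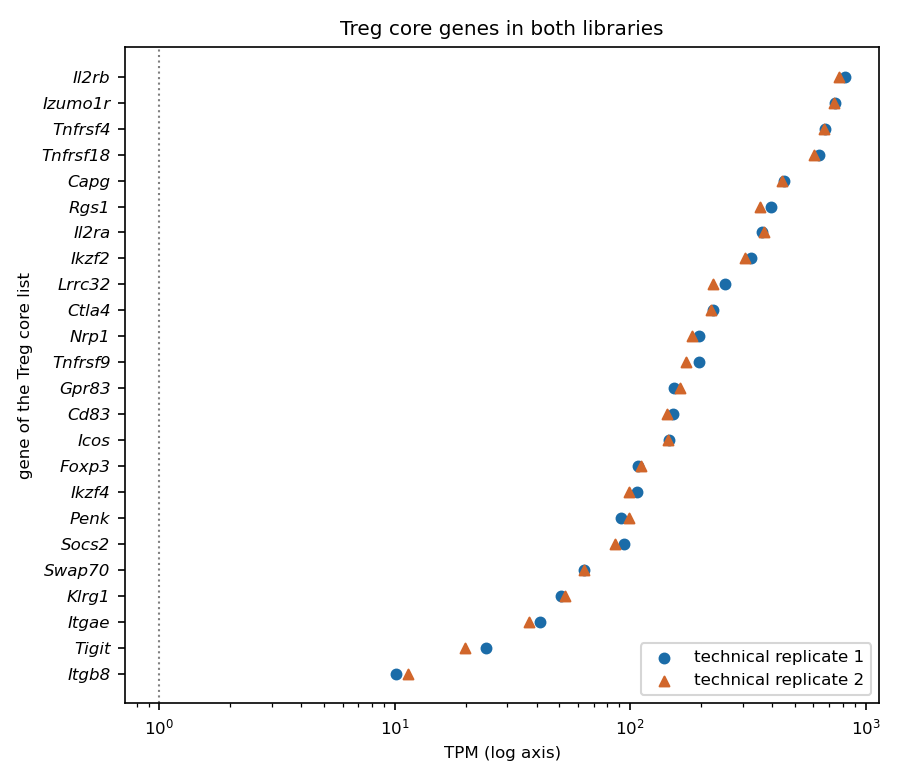
TPM (log axis) of each gene of the Treg core list, with circles for technical replicate 1 and triangles for technical replicate 2; the dotted line marks 1 TPM. All 24 genes lie above the line in both libraries, from Itgb8 at a mean of 10.8 TPM to Il2rb at 795 TPM.

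Of 12 suppressive mediators 11 were detected and Il12a was not. Lgals1, encoding galectin 1, stood at 257 ± 28.8 TPM, the ectonucleotidase Nt5e at 142 ± 10.7 TPM and Tgfb1 at 122 ± 4.68 TPM. Il10 was low, at 3.61 ± 0.891 TPM, and the interleukin 35 subunit gene Ebi3 stood at 24.8 ± 4.0 TPM. The median of the detected members lay at percentile 28.3 among random lists of detected genes, at 52.2 against genes at 0.1 TPM or more, and that of all members at 98.3 against all genes with a read. Effector cytokine genes were largely absent: 3 of 15 were detected, namely Lta at 129 ± 4.15 TPM, Tnf at 34.4 ± 0.551 TPM and Ifng at 3.54 ± 0.325 TPM. Il3, Il5, Il9, Il13, Il17a and Il22 had 0 reads in both libraries, which allows up to 3 reads per library. Il2 was at 1.06 TPM in library 1 and 0.36 TPM in library 2. Library 1 alone had 5 members at 1 TPM or more.

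Genes of resting and lymphoid-homing T cells were expressed at high levels. All 12 members were detected, with a median at percentile 100. The transcription factors Tcf7 and Klf2 stood at 592 ± 62.5 and 561 ± 9.97 TPM, and the lymph node homing receptor Ccr7 at 462 ± 25.2 TPM. Of the 22 effector Treg genes 21 were detected, with a median at percentile 50.1 among random lists of detected genes, at 76.8 against genes at 0.1 TPM or more, and at 99.97 for all members against all genes with a read. Among them Icos stood at 146 ± 1.86 TPM, Pdcd1 at 70.0 ± 3.54 TPM, Ccr8 at 55.5 ± 7.88 TPM and Prdm1 at 11.4 ± 2.52 TPM. Of 6 genes known to be lower in Treg than in other CD4 T cells 5 were detected, with Igfbp4 at 276 ± 5.74 TPM and Il2 the exception.

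Regulators of helper T cell lineages were all detected, 18 of 18. Gata3, the regulator of type 2 helper cells, stood at 93.6 ± 10.7 TPM, and the Foxp3 to Gata3 ratio was 1.18 ± 0.153. Tbx21 and Bcl6, which direct other helper lineages, were lower, at 6.54 ± 2.07 and 13.3 ± 0.863 TPM. Foxp3 exceeded Tbx21 by 13.5-fold in library 1 and 21.8-fold in library 2, and Bcl6 by 8.51-fold and 7.94-fold.

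Signalling genes were well represented. All 13 interleukin 2 and STAT5 response genes were detected, with Il2rg at 1194 ± 44.1 TPM and Cish at 203 ± 22.2 TPM, and all 18 T cell receptor and costimulation genes, with Lck at 1234 ± 53.1 TPM. Of 23 immediate early and stress genes 20 were detected, among them Jund at 677 ± 66.2 TPM and Junb at 487 ± 106 TPM. All 17 interferon-stimulated genes were detected, with Ifi27l2a at 1167 ± 129 TPM. Of 20 proliferation genes 19 were detected, and their median lay at percentile 1.45 among random lists of detected genes, at 14.7 against genes at 0.1 TPM or more, and at 98.8 for all members against all genes with a read. Examples are Mki67 at 4.64 ± 2.37 TPM and Pcna at 122 ± 1.84 TPM. The percentile among detected genes was 5.45 with library 2 alone.

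Metabolic and reference lists were detected nearly in full. All 15 glycolysis genes were detected, with Eno1 at 911 ± 23.9 TPM and Hk2 lowest at 1.19 ± 0.0283 TPM. The 14 matched nuclear genes of oxidative phosphorylation and the 8 genes of fatty acid oxidation were all detected, as were the 12 housekeeping genes. The 13 mitochondrially encoded protein genes took 2.30% of TPM in library 1 and 2.49% in library 2. Of 89 cytosolic ribosomal protein genes 85 were detected, and they took 7.08% and 8.39% of TPM. Of 12 matched RNAs without a poly(A) tail 7 were detected, led by Rn7sk at 51.5 TPM in library 1 and 96.8 TPM in library 2. Of 5 nuclear long noncoding RNAs 3 were detected. All 4 Y-linked genes were detected, with Eif2s3y at 119 ± 19.9 TPM, and Xist stood at 0.04 TPM in library 1 and 0 in library 2, in a sample labelled male.

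The cell type lists ask which other cells the sample could hold. All 15 pan-T genes were detected, with Trbc2 at 3814 ± 3.79 TPM, Trac at 2301 ± 202 TPM and Cd4 at 318 ± 23.9 TPM. Cd4 exceeded Cd8a 198-fold in library 1 and 106-fold in library 2, although Cd8b1 stood at 23.7 ± 0.587 TPM. Trbc exceeded Trdc by 1414 ± 13.7-fold. Of 10 cytotoxic genes 7 were detected, led by Nkg7 at 68.5 ± 5.76 TPM and Ccl5 at 61.4 ± 8.64 TPM. Natural killer genes had 3 of 9 members detected, gamma-delta genes 4 of 6, thymocyte genes 2 of 6 and plasma cell genes 1 of 6. By FPKM 1 thymocyte gene was detected, and with library 1 alone 2 plasma cell genes were. The B cell list had 10 of 13 detected. Within it Ighm, the constant region of the IgM heavy chain, stood at 871 ± 82.9 TPM, while Cd79a was at 8.55 ± 0.304 TPM and Igkc at 31.3 ± 4.54 TPM. The myeloid list had 3 of 12 detected, led by Lyz2 at 13.1 ± 1.82 TPM, and 5 with library 2 alone. Cd74 of the dendritic cell and MHC class II list, with 5 of 11 detected, stood at 131 ± 18.4 TPM. Haemoglobin genes of red cells were present, with Hba-a2 at 134 ± 10.6 TPM and Hbb-bs at 128 ± 2.43 TPM, both members of near-identical gene pairs, and 5 of 10 members of that list were detected. The stroma and endothelium list had 2 of 12 detected, Pecam1 at 125 ± 5.54 TPM and Epcam at 17.7 ± 0.488 TPM. The pan-T median exceeded the B cell median 188-fold and 141-fold in the libraries, and the myeloid median 1124-fold and 932-fold.

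**Figure D2:**
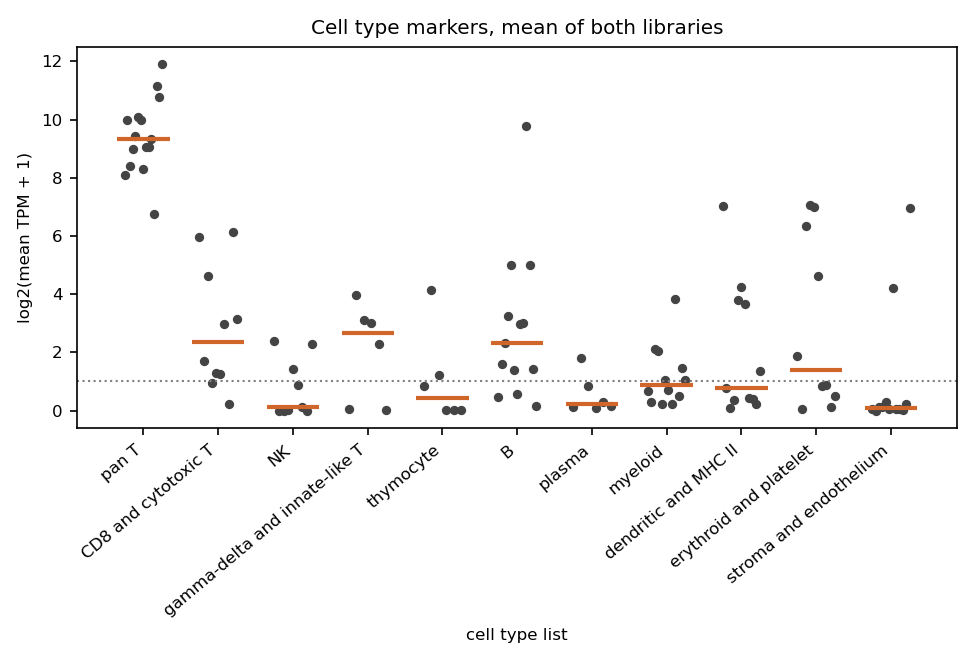
Each point is a marker gene, placed by its log2(mean TPM + 1) over both libraries and grouped by cell type list; bars are list medians and the dotted line corresponds to 1 TPM. All 15 pan-T genes lie above the line, while in the natural killer, thymocyte, plasma, myeloid, dendritic and stroma lists the bar lies below it.

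T cell receptor V segments were diverse. Of 35 beta V segments 23 were detected, and the 12 not detected are all annotated as pseudogenes. Trbv13-2 took 12.6 ± 0.115% and Trbv3 11.9 ± 0.863% of beta V segment TPM. Of 128 alpha V segments 103 were detected, the highest being Trav7d-2 at 3.59 ± 0.340%. Those not detected include pseudogenes and segments given 0 in a single library. Trav11 had 0 and 64.2 estimated counts in libraries 1 and 2, and Trav11d had 58.2 and 0. Alpha V segments include near-identical copies, so single shares are uncertain.

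Transcript estimates were made for 11 genes, of which Ighm was added after its level was seen. They depend on the model that divides reads among overlapping transcripts, an error that the SD between libraries does not cover. Ctla4-201 took 99.2 ± 0.0216% of Ctla4 TPM, and Tgfb1-201 took 82.3 ± 0.267% of Tgfb1 TPM. For Foxp3 the largest share, 49.4 ± 2.5%, went to Foxp3-207, annotated as subject to nonsense-mediated decay, and 26.9 ± 0.422% went to the protein-coding Foxp3-206. For Ikzf2 the largest share, 72.9 ± 3.38%, went to the retained-intron transcript Ikzf2-205. That share was 47.4% by estimated counts, at 50.03% in library 1 and 44.8% in library 2. The protein-coding Ikzf2-201 took 42.2% and 46.2% by estimated counts, so it led in library 2. Leading shares elsewhere were 43.3 ± 1.16% for Ptprc-203, 65.0 ± 0.976% for Il2ra-201, 55.5 ± 0.190% for Cd44-203, 74.3 ± 0.446% for Tcf7-201, 49.4 ± 7.36% for Lef1-203 and 70.1 ± 5.33% for Il7r-201. By estimated counts Cd44-207 led Cd44, and Cd44-203 took 42.2%. For Ighm, Ighm-202 took 62.6 ± 0.439%.

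The libraries were compared to size the technical error. Ribosomal protein genes were higher in library 2, with a median log2 ratio of 0.31 over 87 tested genes, above all 10000 random lists. Of these genes 78 passed the binomial test as higher in library 2 and 3 as higher in library 1. Adjusted over the list alone, 82 passed in either direction, and 3 passed edgeR's exact test with the common dispersion. That dispersion was estimated from the differences between these same libraries. A lack of calls under it, here and below, therefore does not show that a list did not differ. Mitochondrially encoded genes had a median of 0.21, with 11 of 13 called higher in library 2 and mt-Nd3 called higher in library 1, 13 called when adjusted over the list alone, and 0 with the common dispersion. Immediate early and stress genes had a median of -0.13 (percentile 0.14), with 14 of 23 called higher in library 1, 2 called higher in library 2, 16 called in all when adjusted over the list alone, and 0 with the common dispersion. Jun had a log2 ratio of -0.56, Dusp1 -0.55 and Junb -0.37, with edgeR adjusted p of 0.60, 0.635 and 1 under the common dispersion. Interleukin 2 and STAT5 response genes had a median of -0.08, with 9 of 13 called higher in library 1, 1 called higher in library 2, 12 called when adjusted over the list alone, and 0 with the common dispersion. Medians also lay outside the central 95% of random lists for helper lineage regulators at -0.10, dendritic cell and MHC class II genes at -0.34, proliferation genes at 0.14 and interferon-stimulated genes at 0.08. Of these lists the dendritic cell list had 1 gene called with the common dispersion and the others 0. Myeloid genes had a median of -0.35, inside the central 95% of random lists, with 2 called each way and 3 called with the common dispersion. After centring by gene length the ribosomal median was 0.16, still outside the central 95% of its random lists, which were not centred. The mitochondrial median was 0.10, inside its range of -0.07 to 0.13. That of interleukin 2 and STAT5 genes was -0.07, inside its range of -0.08 to 0.08. The helper lineage, dendritic cell, proliferation and interferon lists were not centred. The Treg core median was 0.04, inside the central 95% of random lists, with 9 genes called higher in library 2 and 4 in library 1, and 17 called when adjusted over the list alone. The 6 tested effector cytokine genes had a median of -0.69, also outside the central 95% of random lists, and of -0.44 with a prior count of 5. Il2 and Il21 were called higher in library 1, also when adjusted over the list alone. With the common dispersion Il21 was called and Il2 was not (edgeR adjusted p = 0.347). On M4 Il2 had 2 counts in library 1 and 0 in library 2, and Il21 had 1 and 0, against 24.5 and 8.06 for Il2 and 22 and 0 for Il21 as estimated counts on M21.

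**Figure D3:**
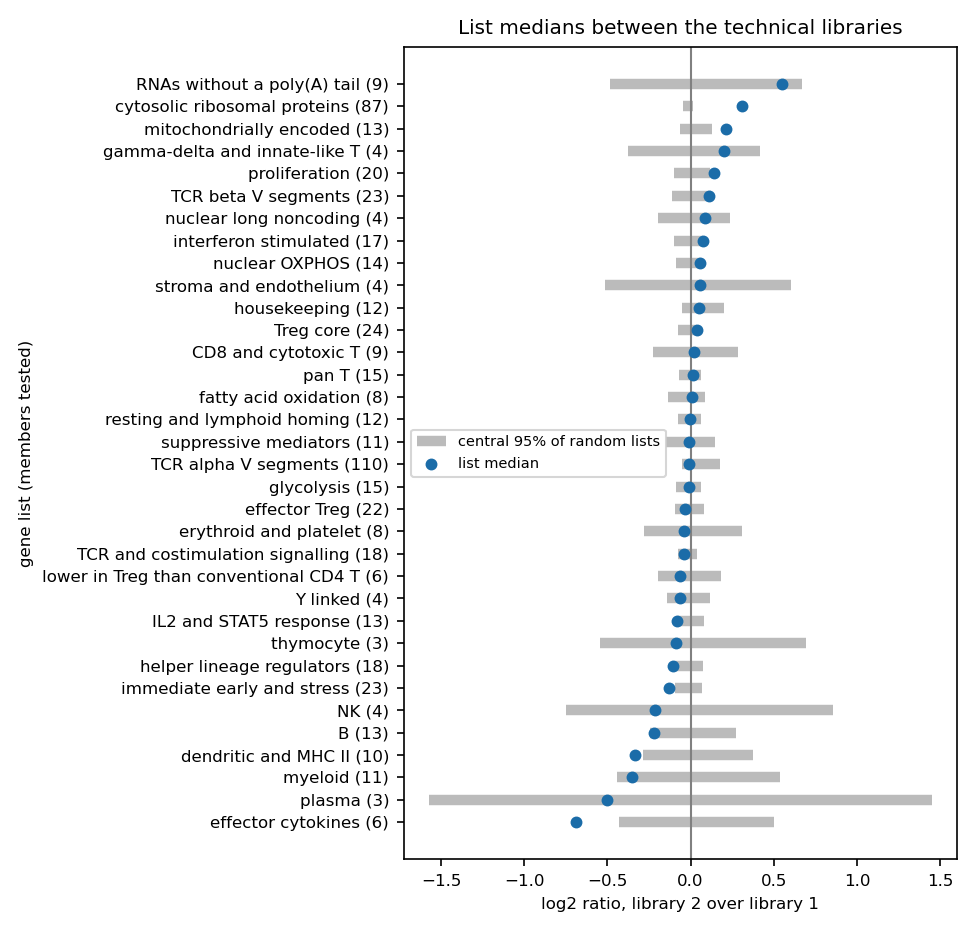
Median log2 ratio of library 2 over library 1 for each gene list (points), with the number of members tested and the central 95% of medians of random lists matched on count (grey bars). Ribosomal protein genes at 0.31 and immediate early genes at -0.13 lie outside their bars.

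Across the 13275 detected genes log2(TPM + 1) had a Pearson r of 0.991 and a Spearman rho of 0.990, a relation across genes, which are not independent replicates. Of these genes 91.5% lay within 1.5-fold. The libraries differed by more than sampling noise, with a chi-square of 12.9 per gene over 18746 genes, so they were kept as separate libraries. The common dispersion corresponded to a coefficient of variation of 15.1%, and of 7.04% with M4 counts, over 12147 genes and fewer reads. The SD of the log2 ratio was 1.62 for genes with 10 to 100 summed counts, where counting alone gives 0.62, and 0.15 for genes with 10000 or more, where counting alone gives 0.02. The exact binomial test called 6834 of 18746 genes, 3228 higher in library 2 and 3606 higher in library 1. With the common dispersion in edgeR's exact test the number was 559, of which 251 were higher in library 2, and 0 Treg core genes were called. All 559 differed by 1.5-fold or more, so the 0 calls cannot exclude smaller differences in Treg core genes. In simulated data the test called few genes changed 2-fold. That test used a dispersion of 0.0312, not 0.0227, on genes drawn from all with at least 100 summed counts. It therefore does not give the power for Treg core genes. With M4 counts, which total 9576557 and 8937887 and flatten for abundant genes, the binomial test called 1747 of 12147 genes, 561 higher in library 2 and 1186 higher in library 1.

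The largest ratios fell mainly on pseudogenes, noncoding genes and members of gene families, whose reads can be divided with similar or overlapping genes. Ywhaq-ps3, Gm43302, Gm26718, Gm2446 and Gm10163 had between 137 and 617 estimated counts in library 1 and 0 in library 2. Trav12n-3, Gm45062, Gm9830 and Gm4294 had 0 in library 1 and between 103 and 150 in library 2, and 5830416I19Rik had 8 and 111. These values are uncertain. Gm43302 (chromosome 5, 105214907 to 105293695) had 419 and 0 estimated counts on M21 but 1206 and 1111 counts on M4.

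The deposited gene tables differed for abundant genes. Over 12040 genes with at least 10 reads in both tables, Spearman rho across genes was 0.891 in library 1 and 0.892 in library 2. Of 468 list genes compared, 230 differed by more than 2-fold in both libraries after scaling, 143 lower on M4 and 87 higher, among them 10 of 24 Treg core genes. In library 1 the median M4 count was 52.3% of the M21 estimated count for genes with 100 to 1000 counts, 41.2% from 1000 to 10000, 17.2% from 10000 to 30000 and 3.58% at 30000 or more. Tmsb4x had 214057 estimated counts and 608 M4 counts in library 1. Foxp3 had 1779 and 1804 M4 counts in the libraries.

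**Figure D4:**
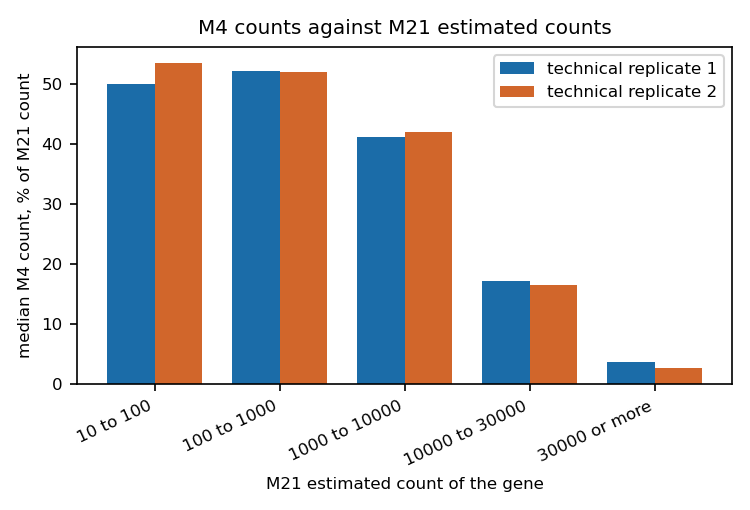
Median M4 count as a percent of the M21 estimated count, for genes binned by their M21 estimated count, in technical replicates 1 and 2. In library 1 the bars fall from 52.3% at 100 to 1000 counts to 3.58% at 30000 or more.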

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

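Reads outside the annotated genes stood above the limit of 3 counts in rows that no comparison used. The rows of the phage phiX174 genome, a common control added to sequencing runs, held 65856 estimated counts in library 1 and 65086 in library 2. The tRNA rows held 2729 and 2879. The other spike-in rows held 0 in both libraries.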

How the results depend on the processing

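The M4 counts in the tests, thinning of library 1 and centring by gene length were chosen after seeing the data. Of the main values, counts of detected genes and list members included, 289 stayed within their limit and 50 moved further. Within that limit, detected genes ran from 10016 at a minimum of 5 TPM to 19189 at 0.1 TPM. Of the levels of single genes and list medians, 59 stayed and 31 moved. By posterior mean TPM Foxp3 was at 102, Il2ra at 342, Ctla4 at 207 and Tnfrsf4 at 623, each beyond its SD between libraries. Others, such as Gata3 and Il10, stayed within it. The limit was 1.5-fold for counts and the spread for most other values. Pearson r, rho and the coefficient of variation have no spread, so they had to be equal to 3 significant digits. For marker ratios and isoform shares a single library always lies within the SD of both libraries, so that outcome was fixed in advance. No value changed sign, but only list medians of log2 ratios could. Among counts of detected list members, 164 of 168 stayed within 1.5-fold. The exceptions were thymocyte genes by FPKM, at 1, and single libraries, which gave 3 to 5 effector cytokine genes, 1 to 2 plasma cell genes and 4 to 5 myeloid genes. The effector Treg percentile was 43.7 by FPKM, 57.4 by posterior mean TPM, 53.7 after rescaling without mitochondrial and ribosomal protein genes, 76.8 against genes at 0.1 TPM or more, 99.97 with all members against all genes, and 43.96 to 46.6 with single libraries. The suppressive percentile was 26.97 with a pseudocount of 0.1, and under those same settings 24.7, 30.1, 28.7, 52.2, 98.3 and 26.5 to 26.7. The proliferation percentile was 98.8 with all members, 14.7 against genes at 0.1 TPM or more, and 1.75 to 5.45 with single libraries. Pearson r between libraries was 0.989 with a pseudocount of 0.1 and 0.992 by posterior mean TPM. The coefficient of variation was 16.0% without a count minimum, 11.3% at 100 summed counts or more and 7.04% with M4 counts, over 12147 genes and fewer reads. Genes differing between the libraries numbered 2191 at 1.5-fold or more, 559 with the common dispersion and 1747 of those 12147 genes with M4 counts. Centring by gene length gave median log2 ratios of 0.16 for ribosomal protein genes, 0.10 for mitochondrially encoded genes, 0.021 for Treg core genes, -0.067 for interleukin 2 and STAT5 genes and -0.78 for effector cytokine genes, which stood at -0.44 with a prior count of 5. By estimated counts, which weight longer transcripts more, the shares were 42.2% for Cd44-203, 99.7% for Ctla4-201, 44.5% for Foxp3-207, 47.4% for Ikzf2-205, 90.4% for Il2ra-201, 84.6% for Il7r-201, 53.2% for Ptprc-203, 80.5% for Tcf7-201 and 89.5% for Tgfb1-201. By posterior mean TPM they were 54.6% for Cd44-203, 98.95% for Ctla4-201 and 81.8% for Tgfb1-201. Without a minimum of reads, rho between M21 and M4 was 0.940 and 0.948. The cause of these moves was not tested. For genes with 10 to 100 summed counts the log2 SD between libraries was 1.62, of which counting alone gives 0.62, so depth is only part of the limit there.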

Other observations

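The tests of sequencing depth, of B cell RNA, of reads shared with another gene, of counting error gene by gene, and of the median difference with each gene left out were chosen only after the result was seen. With 1 group there was no contrast between conditions to test, so the explanations below are technical, RNA from other cells included.

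Further macrophage genes, fixed before their values were seen, were present at low levels. Vcam1, an adhesion molecule of splenic macrophages among other cells, had 324 and 150 reads in libraries 1 and 2, and the complement gene C1qb had 115 and 70. Axl, a receptor for dying cells, had 1547 and 1111. Over the 20 members the sums were 7815 and 6521 (exact binomial p = 1.42e-09), and 15 of 19 tested genes were higher in library 1. That p covers counting error only. The libraries differed by more than counting error across all tested genes, so the p is too small. Cd81, which T cells also express, gave 4278 and 3914 of these reads. The 19 further neutrophil genes, a list from which Ly6g was left out because its counts had been seen, had 492 and 461 reads, and 8 of them could be tested. The granule genes Camp and Ltf had 0 and 2 reads in library 1 and 13 and 53 in library 2, and Il1b had 1 and 17. Mmp9 and G0s2, the neutrophil genes with the most reads, went the other way at 300 and 220 and at 115 and 84, as did Cd177 at 25 and 21, while Anxa1 had 38 and 36.

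In the pattern that led to these lists, the macrophage gene Cd209b had 84 reads in library 1 and 0 in library 2, while the neutrophil genes S100a8 and S100a9 had 0 in library 1 and 32 and 20 in library 2. The further neutrophil median exceeded the further macrophage median by 0.78 on the log2 scale (0.7829), above 98.83% of random pairs of lists matched on count. With each of the 27 tested genes of both lists left out in turn, whatever its direction, the difference ran from 0.21 to 1.36, and for 4 neutrophil genes it fell inside the -0.66 to 0.67 of the central random pairs, so the excess is within its spread. Summed neutrophil reads left counting error undecided (exact binomial p = 0.8458). Gene by gene the mean chi-square of 11.63 exceeded the 2.15 of simulated counts. All tested genes had a mean of 12.9, but that mean is not matched on count. The median chi-square rose from 1.73 at 10 to 100 summed counts to 13.96 at 10000 or more. Whether the excess is particular to this list therefore cannot be told. Different stray myeloid cells in each library and uneven amplification of rare transcripts both may explain the pattern, and cannot be told apart because a single neutrophil gene moves the median by more than the excess.

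Library 1 had a read in 29420 genes and library 2 in 24999. Thinning library 1 to the total of library 2 left 29050, 16.2% more than in library 2, so depth does not account for the gap. In 317 members of gene families of other tissues, a list fixed before its counts were seen, 40 had a read in library 1 and 23 in library 2, a ratio of 1.739. Over all genes, 6929 had a read in library 1 alone and 2508 in library 2 alone, so the excess was not confined to silent families. Reads spread over silent genes, from genomic DNA for example, could contribute, but this ratio cannot tell them from other causes of the excess. Members with a read in a single library numbered 29 in library 1 and 12 in library 2, and all members together had 85 and 60 reads, so the evidence is thin.

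Ighm stood at 930 and 813 TPM, far above Cd79a at 8.55 TPM. RNA from B cells would bring V segments with the constant region, but heavy chain V segments summed to 12.9 and 12.1 TPM, and their V to C ratio was at most 0.03109 of that of the T cell receptor beta chain. The quantifier's posterior SD of the Ighm count was 0% of the count in both libraries, and this argues against reads shared with another gene of the M21 tables. Those tables come from transcriptome alignments, so the SD cannot speak to sequence outside them. A transcript of the Ighm locus without a V segment (chromosome 12, 113418558 to 113422730) may be the source, which was not tested.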
